A study of Mus musculus with 21 samples.

How the data were processed

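RNA from cells sorted out of mouse spleen was measured on 21 Affymetrix arrays, 3 for each of 7 groups. Per the labels, the groups were dendritic cells (DCs) sorted by the 33D1 antibody or by the DEC205 antibody, each from wild-type C57BL/6 mice and from mice injected with Flt3L melanoma, and B cells, CD4 T cells and CD8 T cells of wild-type mice. Flt3L, the ligand of the receptor Flt3, drives the expansion of DCs. The injected mice were killed on days 10 to 12, so the ligand and the tumour came together and cannot be separated here. Groups and replicate numbers were taken from the sample titles. The description field of the B and T cell samples calls them DCs, so their identity was also checked against lineage genes.

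Each array held RNA pooled from 40 to 80 mice (wild-type DCs), 20 mice (DCs of Flt3L mice) or 5 to 8 mice (lymphocytes), per the labels. Total RNA was extracted with Qiagen Mini columns, and biotinylated cRNA was made from 5 ug of it by the standard Affymetrix protocol, per the labels' protocols. The labels do not say how the pools of a group were kept apart. The p-values therefore measure only the spread between these pools, which may be technical in part.

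The deposited signal values are probe set intensities on a linear scale, made with GCOS and MAS5 per the submitters' processing notes. The versions of both programs are not given in the sources used here. The table held 45101 probe sets, and the 2% trimmed mean of every array was 500 signal units, so each array had been scaled to one overall brightness before deposit. Signals ran from a minimum of 0.1 or 0.2 to a maximum between 30350 and 66070, and array medians lay between 121.9 and 204.5. MAS5 detection calls were not used here. With 3 arrays in a group, the number of arrays limits the precision.

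The platform annotation gave exactly 1 gene symbol to 34945 probe sets, several to 932 and none to 9160, and 64 control probe sets were left out. The Entrez identifiers of 34754 named probe sets were found in a RefSeq gene table, and 0 symbols changed in that update. Only probe sets with 1 symbol entered the gene tests. A probe set was kept if its signal exceeded 156.3, the median of the table, on at least 3 of the 21 arrays, which left 29201 probe sets, 23946 of them named. For each gene the probe set with the highest mean over the 21 arrays was used, giving 13284 genes, of which 6068 had more than 1 kept probe set. Among the 305 calls of named genes, 153 had other probe sets, and 0 of these genes had another probe set called in the opposite direction by the same limma test.

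Signals were transformed as log2(signal + 48.6), the offset being the 25th percentile of the table, and the deposited scaling was kept. Differences are on this scale, which understates the change of low genes. All 21 arrays entered 1 linear model with a mean per group (limma 3.58.1 in R 4.3.3, lmFit and eBayes with an intensity trend, 14 residual degrees of freedom). Tests were two-sided, and adjusted p-values were computed by the Benjamini-Hochberg method over the 13284 genes of a contrast. A gene was called at an adjusted p under 0.05. The contrasts were 33D1 minus DEC205 DCs in wild-type and in Flt3L mice, the difference between those contrasts, Flt3L minus wild-type in each subset, B cells minus the mean of both T cell groups, and CD8 minus CD4 T cells. A gene was restricted to a DC subset of wild-type mice if it exceeded the other subset, B cells, CD4 T cells and CD8 T cells, in each of the 4 contrasts by a log2 difference of at least 1 with an adjusted p under 0.05. Errors beside log2 differences are standard errors, and errors beside mean signals are standard deviations of 3 arrays.

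The rule for the genes named in the text, the model and the gene lists were set before the data were examined. For each contrast of DC groups the rule took the 10 highest and the 10 lowest differences among called genes whose 3 arrays of one group all lay above the 3 of the other. It took 5 and 5 for the lymphocyte contrasts and for the difference between the subset contrasts, the latter without the condition on overlap. It also took the 10 genes of each restricted set with the largest smallest difference, up to 4 members of each gene list with the smallest adjusted p, every member of the MHC lists, and the sort markers. Unnamed clones and probe sets with several symbols were passed over.

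The 25 gene lists covered MHC class I presentation, MHC class II presentation, the constitutive proteasome, the lysosome, folding and the unfolded protein response in the endoplasmic reticulum (ER), markers of CD8-positive (type 1) and CD8-negative (type 2) DCs, C-type lectins and related uptake receptors, Toll-like receptors, costimulation and DC maturation, chemokines and their receptors, the interferon response, the cell cycle, and immediate early and heat shock genes. Marker lists of other cells covered B cells, T cells, CD4 T cells, CD8 T cells with cytotoxic genes, NK cells, plasmacytoid DCs, macrophages and monocytes, neutrophils, erythroid cells, platelets and melanoma cells. The lists held 431 genes, of which 368 were tested, 29 lay under the filter and 34 had no probe set with 1 symbol. List shifts were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the 25 lists of a contrast, and again with an estimated correlation. Counts of called members are given over all genes and adjusted over the list alone.

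The settings tried against these choices, listed in advance, were no offset and an offset at the table's median, no filter and a filter at the 75th percentile (526.7), quantile normalization, median centring, the mean of a gene's probe sets, all probe sets, no intensity trend, only the groups compared, array weights, the replicate number as a block, each array left out in turn, a log2 difference of at least 2 for the restricted sets, and Flt3L DCs in place of wild-type DCs in those sets. Added after seeing the data were the array median as a covariate, a replicate block within the Flt3L DC arrays, and 2 settings that left out pairs of wild-type or mixed DC arrays. Median centring moved the median of all genes by 0.14 in B minus T cells and by -0.10 to 0.05 in the other contrasts.

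Whether equal replicate numbers paired the arrays was checked by correlating the deviations of same-numbered arrays from their group means. All 3 correlations exceeded 0.1 in 1 of the 21 pairs of groups, 33D1 and DEC205 DCs of Flt3L mice (0.23, 0.14 and 0.16), so a replicate block within these arrays was fitted as a further setting, while the results reported come from the model without it. With that block, 4247 genes were called between the subsets in Flt3L mice and 17 in the difference between the subset contrasts.

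The limma contrasts, the set restricted to 33D1 DCs and camera at the preset correlation were tried on simulated arrays with the real spreads. Each tested difference was first set to 0, and a small share of the 13284 genes was then changed. Noise was drawn independently for each gene and array. The real subset contrasts called 3046 and 3105 genes, so the recoveries below do not give the power of those contrasts. Of 67 genes changed 2-fold, the model recovered 58.2% in the simulated subset contrast of wild-type mice, 43.3% in that of Flt3L mice, 43.3% for Flt3L against wild-type in 33D1 DCs and 67.2% in DEC205 DCs. For the difference between the subset contrasts it recovered 43.3% of 67 genes at 2-fold and 83.3% of 66 genes at 4-fold.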

Results

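Gene expression was measured in 2 subsets of splenic dendritic cells and in lymphocytes of the mouse. Dendritic cells (DCs) take up antigen and present it to T cells. The 33D1 antibody binds CD8-negative DCs with high CD11c, and the DEC205 antibody binds the CD8-positive DCs. Each subset was sorted from wild-type mice and from mice bearing Flt3L melanoma. B cells, CD4 T cells and CD8 T cells were sorted from wild-type mice. Each of the 7 groups had 3 arrays. The array of each pool gave a signal for 45101 probe sets, with medians between 121.9 and 204.5. Log2 signals of arrays within a group correlated across genes with r between 0.949 and 0.979. Arrays of 33D1 and DEC205 DCs correlated with r between 0.870 and 0.913, and arrays of DCs and lymphocytes with r between 0.715 and 0.827. Genes are not independent replicates, so these correlations describe the arrays only.

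The sort markers separated the groups in the direction of their labels. Ly75, which encodes the DEC205 antigen, had a mean signal of 2973 ± 252 (SD, n = 3) in wild-type DEC205 DCs and 169.3 ± 50.7 in 33D1 DCs, a log2 difference of -3.82 ± 0.22 (SE, adjusted p = 1.37e-11). Cd8a, a chain of the CD8 co-receptor, reached 9584 ± 592 in DEC205 DCs and 302.4 ± 79 in 33D1 DCs (log2 difference -4.80 ± 0.26). Cd4 lay the other way, at 2456 ± 208 in 33D1 DCs and 196.9 ± 180 in DEC205 DCs (3.60 ± 0.30). Itgax, which encodes CD11c, did not pass the test between the subsets (0.46 ± 0.31, adjusted p = 0.351), with 17680 ± 1450 in 33D1 DCs, 12820 ± 726 in DEC205 DCs and 149.3 in B cells. Flt3, the receptor of Flt3L, was lower in 33D1 DCs by -0.60 ± 0.16 (adjusted p = 0.00872). The T cell chains Cd3e and Cd8b1 had low signals in DCs. Cd3e had 50.93 in 33D1 DCs against 7748 ± 1120 in CD4 T cells, and Cd8b1 had 70.97 in DEC205 DCs against 24850 ± 742 in CD8 T cells.

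The first comparison asked how the DC subsets of wild-type mice differ. 33D1 DCs had the higher level of Cd7, a membrane protein of the immunoglobulin superfamily, with 11350 ± 1020 against 239.9 ± 285 in DEC205 DCs (log2 difference 5.83 ± 0.43, adjusted p = 7.14e-10). S100a4, a calcium-binding protein (5.67 ± 0.63), Ryr3, a calcium release channel (5.27 ± 0.43), Tgm2, a transglutaminase (5.02 ± 0.37), Cybb, a subunit of the NADPH oxidase (4.72 ± 0.30), and Sirpa, the receptor of CD47 (4.69 ± 0.34), were also higher in 33D1 DCs. DEC205 DCs had the higher level of Irf8, a transcription factor needed for CD8-positive DCs, with 24730 ± 2040 against 318.6 ± 119 (-6.12 ± 0.42, adjusted p = 2.62e-10). Rab7b, a GTPase of late endosomes (-6.72 ± 0.45), Pdia5, a protein disulfide isomerase (-6.50 ± 0.33), Cd36, a scavenger receptor (-6.34 ± 0.34), and Xcr1, a chemokine receptor of cross-presenting DCs (-5.89 ± 0.42), were higher there too. The rule for named genes also took Bex6 (4.94 ± 0.33), Dtx1 (4.90 ± 0.32), Ddr1 (4.70 ± 0.28) and Rtp4 (4.56 ± 0.39) in 33D1 DCs, and P2ry14 (-5.85 ± 0.40), Plpp1 (-5.62 ± 0.34), Hepacam2 (-5.50 ± 0.23), Olfm1 (-5.41 ± 0.18) and Gcsam (-5.41 ± 0.25) in DEC205 DCs.

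In all, 1489 genes were higher and 1557 lower in wild-type 33D1 DCs than in DEC205 DCs (limma), of which 624 and 568 differed by at least 2-fold. DEC205 replicate 3 held more of several 33D1 transcripts than its fellows, for example a Tgm2 signal of 1413 against 254.9 and 319.5. Without that array and a 33D1 array of Flt3L mice with DEC205 transcripts, 99 of the 101 named genes called here were still called.

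**Figure D1:**
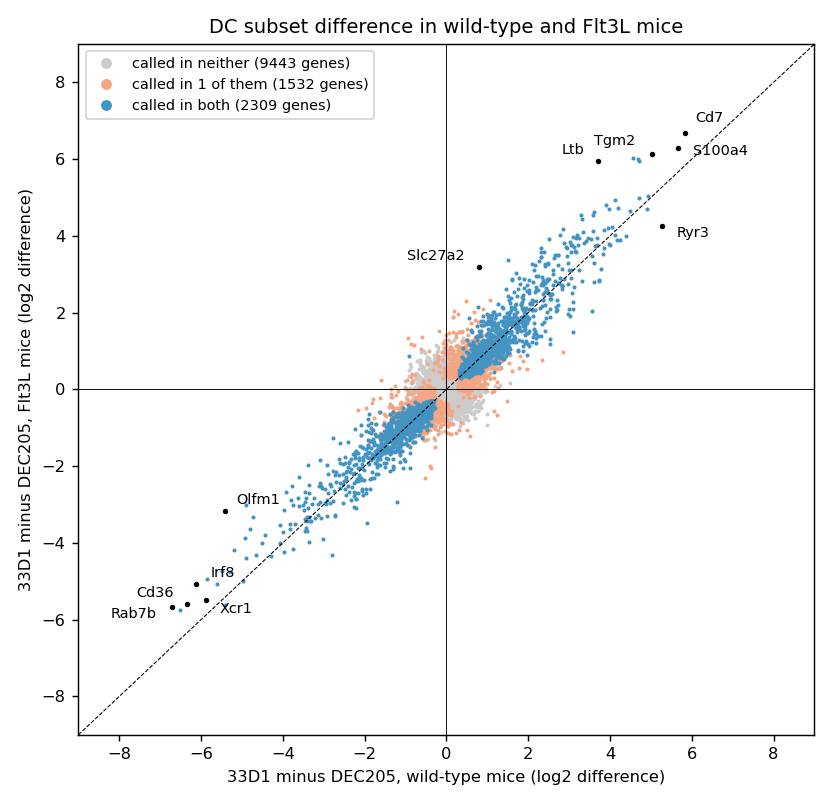
Log2 difference of each gene between 33D1 and DEC205 DCs, in wild-type mice (x axis) and in Flt3L mice (y axis), with points coloured by whether the gene was called in neither, 1 or both contrasts and the dashed line marking equal differences. Cd7 lies at 5.83 and 6.67, and Olfm1 at -5.41 and -3.18.

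Known markers divided the subsets along their CD8 phenotype. Of 14 measured markers of CD8-positive DCs, 13 were lower in 33D1 DCs (13 when adjusted over the list alone), with a median log2 difference of -4.96 (camera, adjusted p = 4.18e-23, and adjusted p = 0.00207 with an estimated correlation). They included Naaa, an amidase (-4.42 ± 0.19), Gcsam, Cd36 and Tlr3, a receptor of double-stranded RNA (-4.98 ± 0.27). Of 14 markers of CD8-negative DCs, 13 were higher and 1 lower (the same numbers adjusted over the list alone), with a median of 3.46 (adjusted p = 5.42e-16, and adjusted p = 0.0056 with an estimated correlation). Ltb, which encodes lymphotoxin beta, differed by 3.70 ± 0.21, Dtx1 by 4.90 ± 0.32 and the lectin Clec4a2 by 4.18 ± 0.31. The markers hold the genes by which the cells were sorted, so they check the labels more than they add to them.

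The study looked at molecules of MHC class I and class II presentation in these same samples, so the directions of these lists are not independent evidence. Of 18 measured class I genes, 13 were lower in wild-type 33D1 DCs (13 adjusted over the list alone), with a median of -0.69 (camera, adjusted p = 8.1e-09). The call was lost with an estimated correlation, at an adjusted p = 0.0711 with an estimated correlation. Both subunits of the peptide transporter were lower, Tap1 by -0.93 ± 0.09 (4002 ± 347 against 7685 ± 446) and Tap2 by -1.0 ± 0.12. So were Pdia3, an oxidoreductase of the peptide loading complex (-1.24 ± 0.14, 6917 ± 540 against 16370 ± 1120), the translocon subunit Sec61a1 (-1.06 ± 0.11) and the immunoproteasome subunits Psmb9 (-1.0 ± 0.14) and Psmb8 (-0.87 ± 0.12). Nlrc5, the transactivator of class I genes (-0.91 ± 0.15), Tapbpl (-0.81 ± 0.17), Calr (-0.72 ± 0.14), Sec61b (-0.66 ± 0.14), Canx (-0.62 ± 0.13), Psme1 (-0.61 ± 0.12) and Tapbp (-0.44 ± 0.11) were lower as well. The class I molecules themselves did not pass the test, with differences of -0.04 ± 0.15 for H2-K1, -0.10 ± 0.17 for H2-D1 and -0.02 ± 0.17 for B2m. Their signals were high in both subsets, with 22860 ± 1610 against 23670 ± 3080 for H2-K1 and 27670 ± 2500 against 28300 ± 5140 for B2m. The highest signal of a wild-type DC array lay between 32910 and 46140. Whether signals so near the top could hide a difference was not tested.

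Of 21 measured class II genes, 9 were higher and 2 lower in wild-type 33D1 DCs (9 and 2 adjusted over the list alone), with a median of 0.24 that did not pass the camera test (adjusted p = 0.0591). The largest difference was that of H2-DMb2, a chain of the peptide exchange factor H2-M, with 13090 ± 494 against 3440 ± 433 (1.92 ± 0.17). The proteases Ctse (1.05 ± 0.15), Ctsc (0.88 ± 0.13), Ctsd (0.79 ± 0.13), Ctsh (0.66 ± 0.16) and Lgmn (0.59 ± 0.17), the thiol reductase Ifi30 (0.60 ± 0.11) and both chains of H2-O, Oa (0.57 ± 0.14) and Ob (0.46 ± 0.10), were higher too. Cst3, an inhibitor of cysteine proteases (-1.30 ± 0.15), and Marchf1, a ligase that removes class II molecules from the surface (-0.86 ± 0.16), were lower. The peptide-binding chains and their chaperone did not pass the test, with -0.05 ± 0.32 for H2-Aa, -0.06 ± 0.37 for H2-Ab1, -0.08 ± 0.26 for H2-Eb1 and -0.10 ± 0.27 for Cd74. The class II shift passed at 0.52 with quantile normalization (adjusted p = 0.00147), at 0.40 without 33D1 replicate 3 (0.0291) and at 0.36 without DEC205 replicate 3 (0.0293), within a range of 0.00147 to 0.362 over the other settings. The number of class II genes called higher was 11 with quantile normalization and 5 with median centring, and that of class I genes called lower 13 and 12.

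**Figure D2:**
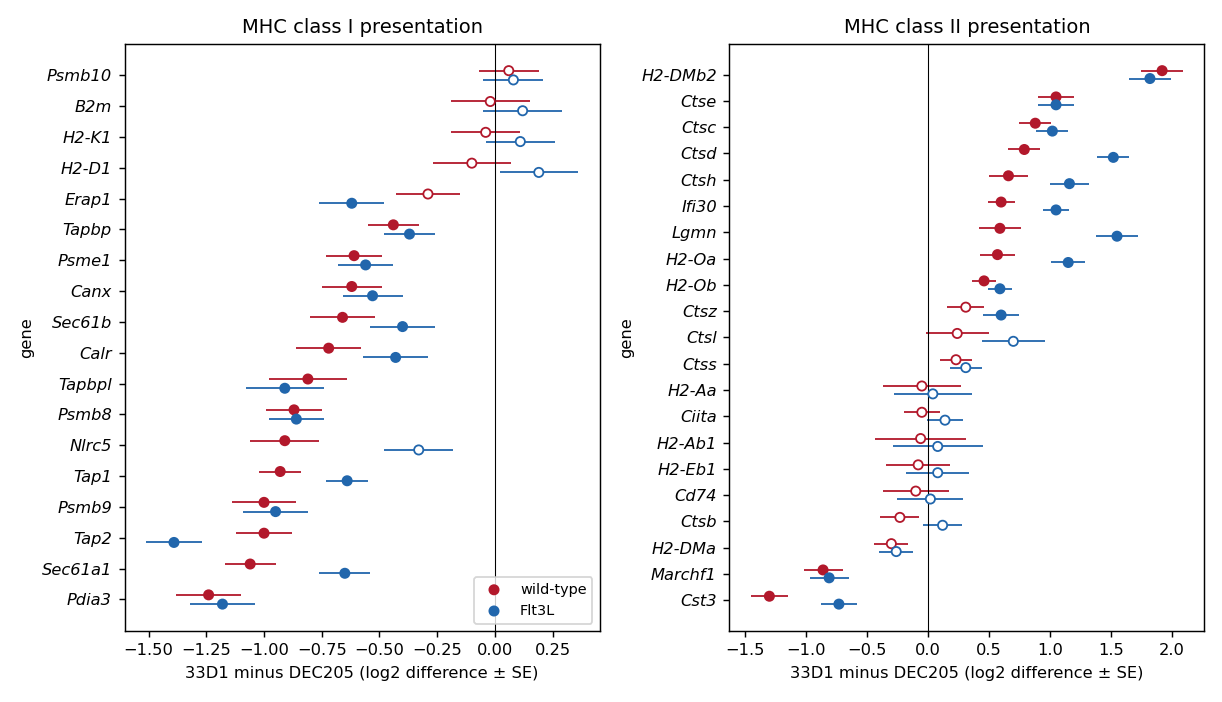
Log2 difference between 33D1 and DEC205 DCs (x axis, bars are standard errors) of each measured gene of MHC class I presentation (left) and class II presentation (right), in wild-type and Flt3L mice, filled where the adjusted p was under 0.05. Tap2 lies at -1.0 and -1.39 and H2-DMb2 at 1.92 and 1.82.

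Other compartments of protein turnover differed as well. In the ER list, 13 of 19 genes were lower in wild-type 33D1 DCs and, adjusted over the list alone, 15 were lower and 1 higher, with a median of -0.77 (camera, adjusted p = 1.29e-08, and adjusted p = 0.0603 with an estimated correlation). Creld2 (-1.85 ± 0.15) and Manf (-1.53 ± 0.15), both induced by ER stress, and the disulfide isomerases Pdia6 (-1.13 ± 0.09) and P4hb (-1.06 ± 0.11) led it. Of 29 constitutive proteasome genes 13 were lower (17 adjusted over the list alone), among them Psmb7 (-0.81 ± 0.16), Psma5 (-0.65 ± 0.11), Psmd12 (-0.61 ± 0.11) and Psma4 (-0.53 ± 0.11). Their median was -0.33 (adjusted p = 1.97e-06, and adjusted p = 0.473 with an estimated correlation). Of 25 lysosome genes, 2 were higher and 11 lower (3 and 11 adjusted over the list alone), with a median of -0.17 (adjusted p = 0.00389, and adjusted p = 0.383 with an estimated correlation). Gusb, beta-glucuronidase, had 1286 against 12830 (-3.28 ± 0.12), and Npc2 (-1.79 ± 0.17) and Psap (-1.44 ± 0.17) were lower, while the cholesterol transporter Npc1 was higher (1.60 ± 0.17).

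Interferon response genes were mostly higher in wild-type 33D1 DCs. Of 24 measured genes 15 were higher and 1 lower (15 and 2 adjusted over the list alone), with a median of 1.07 (camera, adjusted p = 1.92e-08, and adjusted p = 0.216 with an estimated correlation). Rtp4 (4.56 ± 0.39), Oasl2 (3.37 ± 0.36), the antiviral synthetase Oas1a (2.68 ± 0.19) and Ddx58, a sensor of viral RNA (2.47 ± 0.14), had the smallest adjusted p-values. Of 18 immediate early and heat shock genes, Klf4 (2.09 ± 0.37) and Egr2 (1.09 ± 0.37) were higher, and adjusted over the list alone 1 was. Their list did not pass the camera test (median 0.39, adjusted p = 0.234), but it did without the 2 mixed arrays, with a median of 0.76, 3 genes called and an adjusted p of 0.0133 (0.0107 to 0.854 over the other settings). Of 29 cell cycle genes 0 were called by limma and 0 adjusted over the list alone, with 3 at an unadjusted p under 0.05, and the list had a median of 0.32 (adjusted p = 0.169). Without the mixed arrays 3 of them were called and the list passed with a median of 0.49 (adjusted p = 0.00288, and 0.00282 to 0.877 over the other settings).

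Markers of other cells differed in both directions between the subsets of wild-type mice. Of 14 B cell markers 5 were higher and 2 lower in 33D1 DCs (5 and 2 adjusted over the list alone), with Cd22 at 3.04 ± 0.28, Cd79b at 2.34 ± 0.26, Fcrla at -2.07 ± 0.25 and Cd24a at -3.74 ± 0.22 (list median 0.00, camera adjusted p = 0.525). Of 14 T cell markers Cd5 was higher (1.12 ± 0.15) and Cd247 lower (-0.66 ± 0.23), and only the first was called when adjusted over the list alone (median 0.17, adjusted p = 0.411). Of 8 CD4 T cell markers 2 were higher, Cd4 and Icos (0.85 ± 0.25), and 1 lower, Ctla4 (-1.47 ± 0.47), the same numbers as when adjusted over the list alone. That list had a median of -0.01 and a mean of 0.37 (adjusted p = 0.525). Of 15 CD8 T cell and cytotoxic genes 3 were higher, among them Klrd1 (3.63 ± 0.21) and Ccl5 (2.88 ± 0.41), and 2 lower (3 and 3 adjusted over the list alone, median -0.05, adjusted p = 0.932). Of 10 plasmacytoid DC markers 3 were higher and 2 lower (the same adjusted over the list alone), with Spib at 3.47 ± 0.29 and Ccr9 at -3.45 ± 0.26 (median 0.12, adjusted p = 0.921).

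Of 11 macrophage and monocyte markers 1 was higher, Adgre1 (3.15 ± 0.25), and 3 were lower, Hmox1 (-3.09 ± 0.37), Lyz2 (-1.88 ± 0.39) and Vcam1 (-1.38 ± 0.30), the same numbers as when adjusted over the list alone (median -0.18, camera adjusted p = 0.525). Mmp9 was the 1 of 8 neutrophil markers called (2.73 ± 0.29, list median -0.02 and mean 0.32, adjusted p = 0.646). Tfrc (1.65 ± 0.14) and Car2 (1.39 ± 0.21) were the 2 of 6 erythroid markers called (median 0.19, adjusted p = 0.163). Adjusted over the list alone, these 2 lists gave 1 and 2 genes. Of 5 NK cell, 4 platelet and 6 melanoma markers 0 were called by limma, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05, with list medians of 0.00, -0.05 and 0.19 and adjusted p-values of 0.932, 0.932 and 0.921.

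In Flt3L mice the subsets differed by a similar set of genes. Cd7 was again the gene furthest above DEC205 DCs, with 8393 ± 712 against 34 ± 4.24 (6.67 ± 0.43, adjusted p = 8.36e-11), followed by S100a4 (6.30 ± 0.63), Tgm2 (6.14 ± 0.37), Rtp4 (6.02 ± 0.39), Sirpa (5.99 ± 0.34), Ltb (5.95 ± 0.21), Ddr1 (5.95 ± 0.28), Bex6 (5.03 ± 0.33), Cybb (4.98 ± 0.30) and Sirpb1a (4.94 ± 0.37). Pdia5 (-5.74 ± 0.33), Rab7b (-5.67 ± 0.45), Gcsam (-5.61 ± 0.25), Cd36 (-5.60 ± 0.34), Xcr1 (-5.50 ± 0.42), Irf8 (-5.08 ± 0.42), Plpp1 (-5.07 ± 0.34), Tlr3 (-4.99 ± 0.27), P2ry14 (-4.94 ± 0.40) and Cadm1 (-4.75 ± 0.29) were furthest below. 33D1 replicate 3 of Flt3L mice held more of these DEC205 transcripts than its fellows, with a Rab7b signal of 527.1 against 74.6 and 75. The limma fit called 1546 genes higher and 1559 lower, 686 and 521 of them by at least 2-fold.

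Between the contrasts of wild-type and Flt3L mice, which share no arrays, 1124 genes were called higher in both, where independent lists would share 173.3, and 1184 lower in both, where they would share 182.7. Both contrasts use the same estimate of a gene's spread, so their calls are not fully independent. The log2 differences correlated across genes with r = 0.882 (Spearman's rho 0.726). The 1 gene called in opposite directions was the chemokine Ccl6, at -0.91 ± 0.26 in wild-type and 0.88 ± 0.26 in Flt3L mice, and it was picked after its values were seen. The direct test of this change did not pass (adjusted p = 0.0681).

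Markers of the subsets and class I genes differed in the same directions in Flt3L mice. Of the markers of CD8-positive DCs 13 of 14 were lower (14 adjusted over the list alone, median -4.31, camera adjusted p = 4.25e-21, and adjusted p = 0.00323 with an estimated correlation). Of those of CD8-negative DCs 13 were higher and 1 lower (the same adjusted over the list alone, median 3.84, adjusted p = 3.36e-17, and adjusted p = 0.00402 with an estimated correlation). Class I genes were again lower, 13 of 18 (13 adjusted over the list alone, median -0.54, adjusted p = 1.06e-06, and adjusted p = 0.13 with an estimated correlation), among them Tap2 (-1.39 ± 0.12), Pdia3 (-1.18 ± 0.14), Psmb9 (-0.95 ± 0.14), Psmb8 (-0.86 ± 0.12) and Erap1, which trims peptides (-0.62 ± 0.14). Of the 21 class II genes 10 were higher and 2 lower (12 and 2 adjusted over the list alone), with a median of 0.59 (adjusted p = 0.000152, and adjusted p = 0.0522 with an estimated correlation). H2-DMb2 (1.82 ± 0.17), Lgmn (1.55 ± 0.17), Ctsd (1.52 ± 0.13), Ctsh (1.16 ± 0.16), the Oa chain of H2-O (1.15 ± 0.14) and Ifi30 (1.05 ± 0.11) were among the higher genes, while H2-Aa (0.04 ± 0.32) and H2-K1 (0.11 ± 0.15) did not pass. The class II count was 11 with quantile normalization and 9 with median centring, and the class I count 13 and 10.

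In the other lists of presentation and stress, 11 of 19 ER genes were lower in 33D1 DCs of Flt3L mice and, adjusted over the list alone, 2 were higher and 13 lower (median -0.68, camera adjusted p = 7.87e-06, and adjusted p = 0.13 with an estimated correlation). Of the proteasome genes 12 of 29 were lower (13 adjusted over the list alone, median -0.28, adjusted p = 1.28e-05, and adjusted p = 0.505 with an estimated correlation). Of the lysosome genes 4 were higher and 11 lower (the same adjusted over the list alone, median -0.15, adjusted p = 0.0414, and adjusted p = 0.551 with an estimated correlation), with Gusb at -3.00 ± 0.12. Of the interferon genes 15 of 24 were higher, with 16 higher and 1 lower adjusted over the list alone (median 0.95, adjusted p = 4.02e-09, and adjusted p = 0.142 with an estimated correlation). Rtp4 (6.02 ± 0.39), Oas2 (3.92 ± 0.30) and Ifit3 (2.96 ± 0.24) were among them. Immediate early genes were higher in 6 of 18 cases (7 adjusted over the list alone, median 0.84, adjusted p = 0.0133, and adjusted p = 0.656 with an estimated correlation), with Klf4 at 2.06 ± 0.37 and Egr1 at 2.02 ± 0.39. The mean level of that list also varied within groups, for example from 11.55 to 12.77 on the log2 scale in wild-type DEC205 DCs. The highest of these was that of replicate 3, the array with more 33D1 transcripts.

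To look for molecules that 33D1 DCs have and other sorted cells lack, each subset was set against the other and against the 3 lymphocyte groups. The gene with the largest margin in 33D1 DCs was Tgm2, with 17750 ± 789 in 33D1 DCs, 662.4 ± 651 in DEC205 DCs, 163.2 in B cells, 139.8 in CD4 T cells and 58.23 in CD8 T cells, so that the smallest of the 4 log2 differences was 5.02. It was followed by Bex6 (4.94), Ryr3 (4.70), Sirpa (4.69), the elastase Mmp12 (4.25), Npl (4.23), the lectin receptor Clec4a2 (4.18), Sirpb1a (4.12), the prostaglandin receptor Ptger3 (3.98) and Ube2e2 (3.95). Of these, Sirpa, Clec4a2, Sirpb1a and Ptger3 encode membrane receptors, and Ryr3 encodes a channel of intracellular membranes. In DEC205 DCs the leading genes were Rab7b (6.72), Pdia5 (6.27), Xcr1 (5.88), Olfm1 (5.41), the adhesion molecule Cadm1 (5.26), the chemokine Cxcl9 (5.20), Gcsam (5.18), Tlr3 (4.98), P2ry14 (4.80) and Plpp1 (4.6).

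In total 244 genes were restricted to 33D1 DCs and 347 to DEC205 DCs, with an adjusted p under 0.05 in each of the 4 limma contrasts. With DCs of Flt3L mice in their place the sets held 246 and 319 genes and shared 198 and 270 genes with the first sets, where independent sets would share 4.52 and 8.33. Both comparisons use the same lymphocyte arrays, so their overlap is not independent. Cybb was high in 33D1 DCs yet not restricted, with 7333 in B cells. Cd7 was restricted by a smaller margin (1.76), with 3470 in CD8 T cells. Requiring a log2 difference of at least 2 left 87 and 98 genes. In simulated arrays the rule recovered 1.49% of 67 genes raised 2-fold in 33D1 DCs and 89.6% of 67 genes raised 4-fold.

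**Figure D3:**
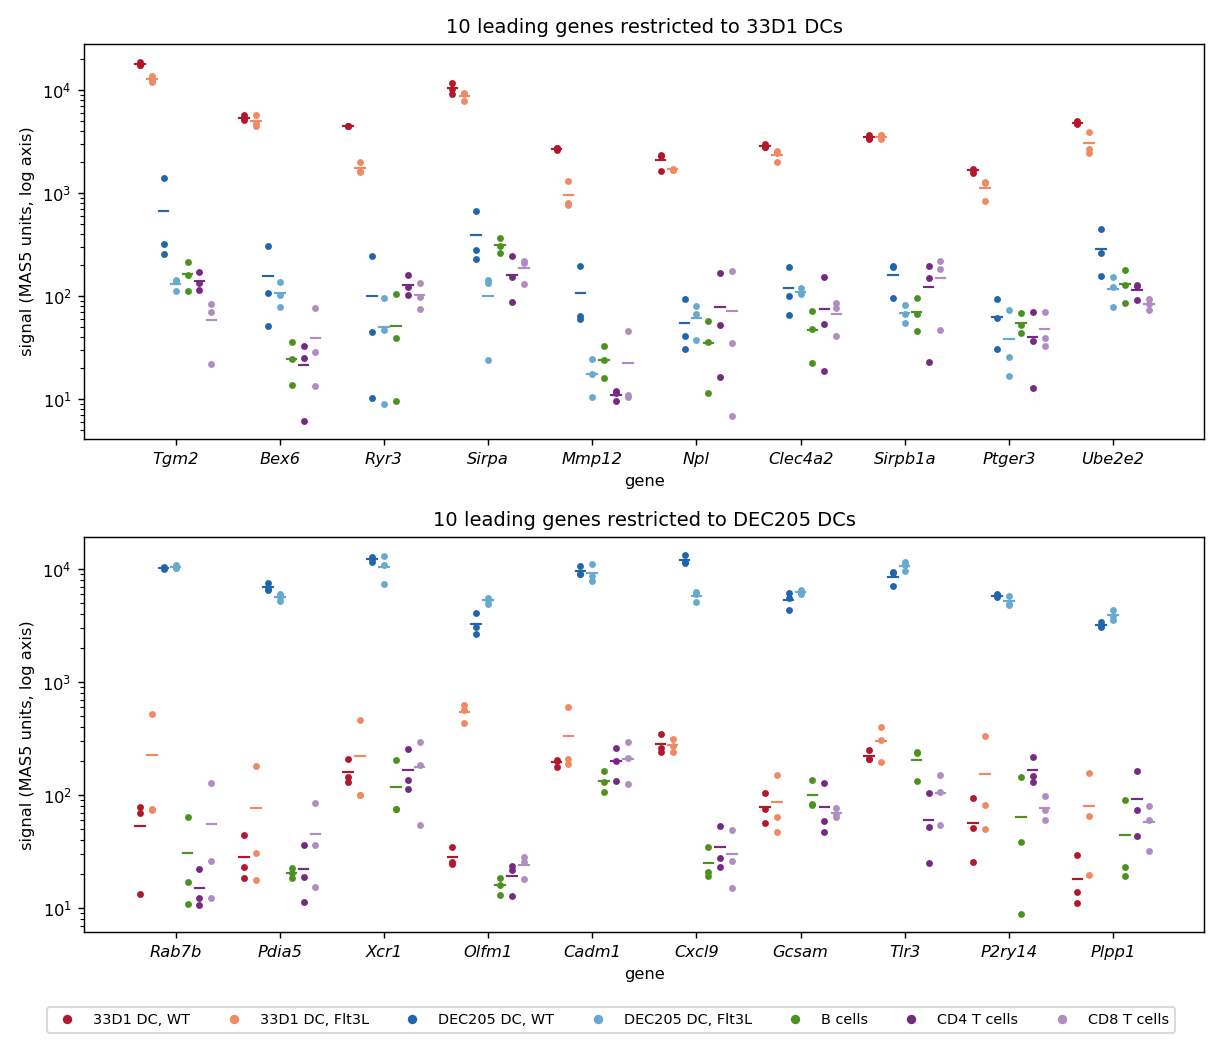
Signal (log axis, points are arrays and lines are group means) of the 10 leading genes restricted to 33D1 DCs (top) and to DEC205 DCs (bottom) in the 7 groups. Tgm2 averaged 17750 in wild-type 33D1 DCs and 163.2 in B cells.

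The Flt3L mice were compared with wild-type mice within each subset, with the ligand and the tumour acting together. In 33D1 DCs, Olfm1, a secreted glycoprotein that was otherwise a gene of DEC205 DCs, rose from 28.37 ± 5.86 to 544.7 ± 101 (2.93 ± 0.18, adjusted p = 4.14e-09). The fatty acid transporter Slc27a2 (2.39 ± 0.29), Slfn1 (2.34 ± 0.30), the oxidase Xdh (2.04 ± 0.27), Ahnak (1.95 ± 0.33), the growth factor receptor Fgfr1 (1.94 ± 0.25), the chemokine Ccl9 (1.80 ± 0.30), the low-affinity IgE receptor Fcer2a (1.64 ± 0.30) and the chemokine Ccl6 (1.60 ± 0.26) rose as well. Esam, an adhesion molecule that marks a CD8-negative DC subset, fell from 2460 ± 271 to 716.2 ± 95.5 (-1.72 ± 0.20, adjusted p = 8.78e-05). Spats2 (-1.87 ± 0.31), Scn3a (-1.66), Mmp12 (-1.49 ± 0.29, from 2702 to 961.6) and Max (-1.40) also fell.

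In 33D1 DCs limma called 111 genes higher and 22 lower in Flt3L mice, 51 and 16 of them by at least 2-fold. The call count depended on the arrays: it was 80 without the 2 mixed arrays, when 19 of the 29 named genes called here were still called, and 51 without Flt3L replicate 2. With array weights 427 genes were called, and with median centring 63.

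Interferon response genes rose in 33D1 DCs of Flt3L mice, 6 of 24 over all genes and 17 adjusted over the list alone, with a median of 0.72 (camera, adjusted p = 3.51e-16, and adjusted p = 0.154 with an estimated correlation). Oasl2 (1.51 ± 0.36), Mx1 (0.91 ± 0.19), Oasl1 (0.84 ± 0.18) and Oas1a (0.83 ± 0.19) were among them. Of 29 cell cycle genes 2 rose, the centromere histone Cenpa (0.80 ± 0.19, adjusted p = 0.0405) and the mitotic kinase Plk1 (1.01 ± 0.24, adjusted p = 0.0422), and 16 when adjusted over the list alone (median 0.78, adjusted p = 3.95e-15, and adjusted p = 0.288 with an estimated correlation). In the CD8-negative marker list Esam fell, with 1 gene higher and 3 lower adjusted over the list alone (median -0.25, adjusted p = 0.0292, and adjusted p = 0.657 with an estimated correlation). The costimulation list shifted by a median of -0.23 (adjusted p = 0.0266, and adjusted p = 0.423 with an estimated correlation), with 0 of 21 genes called by limma, 3 at an unadjusted p under 0.05 and 1 lower adjusted over the list alone. The erythroid list shifted by -0.37 (adjusted p = 0.0292, and adjusted p = 0.423 with an estimated correlation). None of the class I genes was called, with 3 at an unadjusted p under 0.05 and 1 adjusted over the list alone, and none of the class II genes, with 3 at each of these levels. Of 14 B cell markers Fcer2a and Cd24a (0.92 ± 0.22) rose, with 2 higher and 2 lower adjusted over the list alone (median -0.12, adjusted p = 0.78). Of 10 plasmacytoid DC markers Bst2 rose (0.96 ± 0.23), also when adjusted over the list alone (median 0.18, adjusted p = 0.144). Without the mixed arrays, and so with fewer arrays, Bst2 had 0.90 and Cd24a 0.65, and neither was called. Melanoma markers had a median of -0.01, and 0 of 6 were called, with 1 at an unadjusted p under 0.05.

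In DEC205 DCs of Flt3L mice, Lifr, a receptor subunit of leukemia inhibitory factor, rose from 18.53 to 339 ± 131 (2.47 ± 0.40, adjusted p = 0.00142). The interferon-induced gene Ifi27l2a rose from 659.4 ± 231 to 3577 ± 1170 (2.35 ± 0.25). Ddit4 (2.18 ± 0.31) and Fkbp5 (1.70 ± 0.18), both induced by glucocorticoids, Fgfr1 (1.77 ± 0.25) and the galectin Lgals9 (1.74 ± 0.16) rose too. Serpinb2, an inhibitor of plasminogen activators, fell from 1828 ± 64.7 to 267 ± 107 (-2.63 ± 0.27, adjusted p = 1.03e-05), and Gp2 (-2.69 ± 0.31), Ltb (-2.50 ± 0.21), Mefv (-2.28 ± 0.24) and Ms4a1, which encodes the B cell antigen CD20 (-1.68 ± 0.29), fell with it. Limma called 163 genes higher and 117 lower, 40 and 61 of them by at least 2-fold.

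The share of DEC205 genes called higher moved with the arrays used. It was 58.2% of 280 genes with all arrays, 70.8% of 192 without the 2 mixed arrays and 40.5% of 153 without the brightest array of each wild-type DC subset. Without the mixed arrays 26 of the 42 named genes called here were still called, with median centring 90 genes were called, and without Flt3L replicate 2 the count was 93.

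Cell cycle genes rose in DEC205 DCs as they had in 33D1 DCs, 5 of 29 over all genes and 19 adjusted over the list alone, with a median of 0.73 (camera, adjusted p = 4.85e-17, and adjusted p = 0.1 with an estimated correlation). They included the ribonucleotide reductase subunit Rrm1 (0.87 ± 0.16), the replication helicase subunit Mcm6 (0.74 ± 0.16), Ccne1 (0.91 ± 0.23) and Cenpa (0.73 ± 0.19). Interferon genes rose in 4 of 24 cases, with 13 higher and 1 lower adjusted over the list alone (median 0.44, adjusted p = 3.54e-09, and adjusted p = 0.134 with an estimated correlation), led by Oas1a (1.47 ± 0.19), Xaf1 (1.38 ± 0.19), Isg20 (1.45 ± 0.24) and Usp18 (1.2 ± 0.25).

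Markers of CD8-negative DCs fell in DEC205 DCs, 6 of 14 over all genes and 8 adjusted over the list alone, with a median of -0.81 (camera, adjusted p = 7.82e-09, and adjusted p = 0.0678 with an estimated correlation). Ltb, Cd4 (-1.50 ± 0.30), Sirpa (-1.55 ± 0.34) and Cd209a (-1.14 ± 0.26) were among them. The 198 genes restricted to 33D1 DCs in both kinds of mice also lay at a lower percentage of the 33D1 level in every Flt3L DEC205 array. Their median was 19.34%, 19.69% and 24.11% of the wild-type 33D1 level in wild-type DEC205 arrays. In Flt3L DEC205 arrays it was 16.61%, 17.82% and 18.43% of the Flt3L 33D1 level. The 33D1 level is not the same in both kinds of mice, so these percentages do not by themselves show lower signals. Whether less RNA of 33D1 DCs in the Flt3L arrays lowered the markers was not tested. Wild-type DEC205 replicate 3 held 33D1 transcripts, and without the 2 mixed arrays the list had a median of -0.42 with 2 genes called (adjusted p = 4.48e-05, and 1.64e-12 to 0.0678 over the other settings), while Sirpa (-1.14) and Cd209a (-0.94) kept most of their difference but were no longer called with fewer arrays (adjusted p = 0.134 and 0.161, the highest over the other settings, against lowest values of 0.00178 and 0.00393). The costimulation list fell by a median of -0.34 with 2 of 21 genes called, Traf1 (-1.01 ± 0.24) and Relb (-0.73 ± 0.18), and 9 adjusted over the list alone (adjusted p = 2.82e-05, and adjusted p = 0.0678 with an estimated correlation). Macrophage markers fell in 2 of 11 cases, Hmox1 (-1.56 ± 0.37) and Vcam1 (-1.21 ± 0.30), and in 5 adjusted over the list alone (median -0.50, adjusted p = 0.00152, and adjusted p = 0.194 with an estimated correlation). Immediate early genes fell in 3 of 18 cases, Ier3 (-1.86 ± 0.43), Egr1 (-1.57 ± 0.39) and Egr2 (-1.52 ± 0.37), and in 3 adjusted over the list alone (median -0.68, adjusted p = 0.000161, and adjusted p = 0.427 with an estimated correlation). Without the mixed arrays, and so with fewer arrays, 0 genes of these 3 lists were called by limma, although the log2 differences stayed at -1.16 for Vcam1, -1.35 for Hmox1, -0.89 for Traf1, -0.54 for Relb, -1.52 for Ier3, -1.24 for Egr1 and -1.19 for Egr2. The costimulation (-0.31, adjusted p = 0.00245, and 1.39e-08 to 0.0678 over the other settings) and macrophage lists (-0.38, adjusted p = 0.0164, and 3.7e-05 to 0.194) still passed, and the immediate early list did not, with a median of -0.16 (adjusted p = 0.134, and 2.1e-08 to 0.427 over the other settings).

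Class II genes fell in DEC205 DCs of Flt3L mice in 2 of 21 cases, the Oa chain of H2-O (-0.70 ± 0.14) and Ctsd (-0.65 ± 0.13), with 1 higher and 4 lower adjusted over the list alone (median -0.18, camera adjusted p = 0.000161, and adjusted p = 0.0678 with an estimated correlation). With median centring 0 of them were called. Without the mixed arrays 1 was, and Ctsd had -0.57 (limma, adjusted p = 0.0702). The ER list had a median of -0.16 (adjusted p = 7.65e-05, and adjusted p = 0.143 with an estimated correlation), with 0 genes called by limma, 8 at an unadjusted p under 0.05 and 2 adjusted over the list alone. Of the class I genes 0 were called, with 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone (median -0.09, adjusted p = 0.173). Between the Flt3L effects in the 2 subsets, which share no arrays, 39 genes rose in both, where independent lists would share 1.36, and 5 fell in both, where they would share 0.194. Both effects use the same estimate of a gene's spread, and the Flt3L arrays of the subsets correlated by replicate number. Their calls are therefore not independent, and the overlap is described only.

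Whether the subset difference itself changed with Flt3L was tested directly by the difference between the 2 subset contrasts. It passed for Olfm1 (2.23 ± 0.26, adjusted p = 0.000352), whose log2 difference went from -5.41 in wild-type to -3.18 in Flt3L mice as its level rose in 33D1 DCs. It passed for Ltb (2.25 ± 0.30, adjusted p = 0.00112), which went from 3.70 to 5.95 as its level in DEC205 DCs fell from 1211 ± 456 to 169.7 ± 61.5. Slc27a2 (2.40 ± 0.41, from 0.80 to 3.19), the actin regulator Mtss1 (1.96 ± 0.35, from -0.59 to 1.37) and Spry2, an inhibitor of growth factor signalling (1.87 ± 0.34, from 0.18 to 2.05), moved the same way. Rtl8c (-1.55 ± 0.23, from -1.94 to -3.49) and Lgals9 (-1.23 ± 0.23, from 1.27 to 0.04) moved the other way.

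The test called 12 genes with a positive and 2 with a negative change (limma), with 629 genes at an unadjusted p under 0.05. The class II list shifted by a median of 0.16 (camera, adjusted p = 1.48e-05, and adjusted p = 0.0475 with an estimated correlation), with 0 genes called, 6 at an unadjusted p under 0.05 and 4 adjusted over the list alone. It was the only 1 of 9 lists with an adjusted p under 0.05 that also passed with an estimated correlation. The others were markers of CD8-positive (median 0.59), CD8-negative (0.59) and plasmacytoid DCs (0.36), immediate early genes (0.46), C-type lectins (0.42), CD8 T cell genes (0.38), chemokines (0.37) and ER genes (0.08). Without the 2 mixed arrays only class II (0.12, camera adjusted p = 0.007) and chemokines (0.27, adjusted p = 0.0212) of these 9 still passed. The class I list did not pass (median 0.09, adjusted p = 0.0932). Without the 2 mixed arrays 3 genes were called and with no offset 2, and only Ltb among the 7 genes named here was called under every setting tried.

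**Figure D4:**
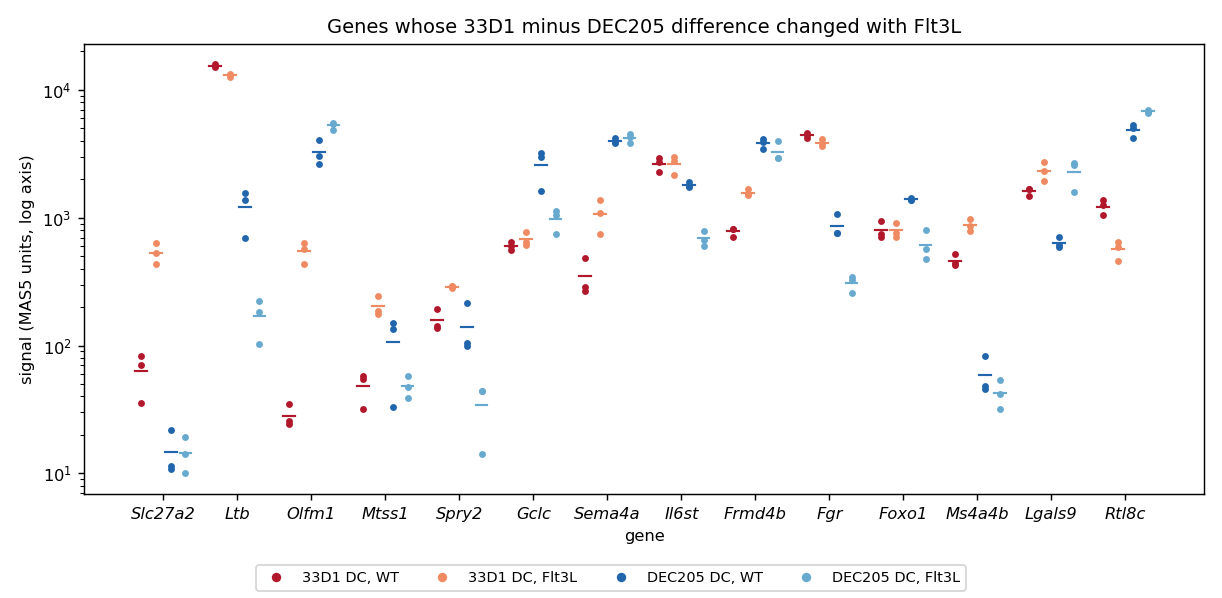
Signal (log axis, points are arrays and lines are group means) in the 4 DC groups of the 14 genes whose subset difference changed with Flt3L. Ltb fell from 1211 to 169.7 in DEC205 DCs and Olfm1 rose from 28.37 to 544.7 in 33D1 DCs.

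The lymphocyte groups served as the cells to subtract, and their own contrasts carried the lineage genes of their labels. B cells exceeded T cells in the light chain gene Iglv1 (7.71 ± 0.27), Igkv8-30 (7.11 ± 0.30), the receptor subunit Cd79a (7.05 ± 0.32, 29190 ± 1560 in B cells), Ly86 (6.95 ± 0.28) and Ly6d (6.93 ± 0.36). T cells exceeded B cells in the receptor subunits Cd3d (-8.35 ± 0.13, adjusted p = 1.2e-21) and Cd3g (-7.51 ± 0.24), Trbv1 (-7.74 ± 0.21), Ms4a4b (-7.22 ± 0.12) and Dapl1 (-7.07 ± 0.20). CD8 T cells exceeded CD4 T cells in Cd8a (5.94 ± 0.26), Cd8b1 (5.53 ± 0.28), the integrin Itgae (4.04 ± 0.27), Plac8 (3.91 ± 0.24) and Ccr9 (3.70 ± 0.26). CD4 T cells had more Cd4 (-6.27 ± 0.30), St8sia6 (-3.81 ± 0.21), the transcription factor Maf (-3.77 ± 0.35), Pdlim4 (-3.74 ± 0.32) and Nrp1 (-2.76 ± 0.24).

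Limma called 1731 genes higher and 1837 lower in B than in T cells, and with median centring, which shifted this contrast by 0.14, 1736 and 1129. Between the T cell groups it called 215 genes higher and 214 lower in CD8 T cells, and with only these arrays in the fit 125 and 90.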

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

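Some of the tests weighed here were chosen only after the result was seen, namely the search for transcripts of the other DC subset, its repeat on genes at a low baseline, the same shares in the other DC groups, the sorting of the regroupings by whether they kept a subset, the interaction genes without the mixed arrays, and the comparison of the cell cycle list with markers of other cells. The array median as a covariate was also added after the data were seen. A test of the difference between the subset contrasts picked out 14 genes whose 33D1 minus DEC205 difference was not the same in Flt3L and wild-type mice. The log2 changes were 2.40 for Slc27a2, 2.25 for Ltb, 2.23 for Olfm1, 1.96 for Mtss1 and 1.87 for Spry2, and -1.23 for Lgals9 and -1.55 for Rtl8c. The other genes, outside the rule for named genes and given here because the test called them, were Gclc (1.48), Sema4a (1.43), Il6st (1.32), Frmd4b (1.19), Fgr (1.15), Foxo1 (1.15) and Ms4a4b (1.08). By the same test the MHC class II list had a median change of 0.16. Among probe sets without a single gene name, which entered no gene test, 48 met the conditions for restriction to 33D1 DCs and 57 those for DEC205 DCs.

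A change of the subset difference with Flt3L could come from RNA of the other subset in some arrays, from array brightness, from chance, or from the Flt3L mice themselves. All 14 genes kept most of their log2 difference without the mixed arrays. They had been picked by a test that used those arrays and favours genes whose arrays vary little. Their values therefore cannot decide whether RNA of the other subset in those 2 arrays played a part. Without these arrays, and so with fewer arrays, 3 genes were called, 2 with a positive and 1 with a negative change. With the array median as a covariate all 14 kept most of their log2 difference. Array medians were similar in Flt3L and wild-type mice, at 136.7 to 162.3 and 144.8 to 180.7 in 33D1 DCs. In DEC205 DCs they were 121.9 to 148.7 and 131.4 to 168.1. The covariate could therefore hardly move the differences, and it does not test brightness. RNA of the other subset at another level in whole groups was not tested. Genes of the other subset had medians of 21.6% to 22.11% of its level in wild-type and 23.32% to 24.82% in Flt3L 33D1 arrays. In DEC205 arrays they had 19.34% to 24.11% and 16.61% to 18.43%. Each array was set against the other subset from the same kind of mice, so a changed percentage can also come from that other subset. Among 100 regroupings of the DC arrays, 9 gave at least as many calls as the real one, itself included, which gave 14, and the highest gave 63, but the 8 others all kept the real grouping of a subset and so carried its Flt3L effect. Of 80 that mixed both subsets 0 reached 14 (highest 2), and since mixing adds real effects to the spread, chance is left undecided. Whether the ligand or the tumour lies behind them stays open, since they came together.

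DEC205 replicate 3 of wild-type mice and 33D1 replicate 3 of Flt3L mice had higher signals of transcripts of the other subset than their fellows. In the DEC205 array 71.95% of 246 genes of the other subset lay above the mean of its fellows, and in the 33D1 array 63.4% of 347 did, where the 6 arrays of the other DC groups gave 47.34% to 50%. Neither share decides by itself, but among genes at a low baseline 100% of 22 and 93.1% of 29 were higher, against 44.83% to 62.96% in those 6 arrays, which fits such RNA at a median share of 4.246% and 2.758%. Dim lymphocyte genes moved by -0.05 in the DEC205 array, which argues against array brightness there, and by 0.03 in the 33D1 array, which leaves it undecided. Whether such RNA came from the sort or from cells between the subsets was not tested.

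The cell cycle list was higher with Flt3L in both subsets, which may reflect division of DCs, dividing cells of another type, or array brightness. With the array median as a covariate its median was 0.76 in 33D1 and 0.72 in DEC205 DCs, against 0.78 and 0.73 without it. Array medians were similar in Flt3L and wild-type mice, so the covariate could hardly move the list and does not test brightness. The highest median among marker lists of 9 other cell types was 0.18 in 33D1 DCs (plasmacytoid DCs) and -0.03 in DEC205 DCs (T cells), which argues against these cells as a whole. Even so, Fcer2a (1.64) and Cd24a (0.92) of the B cell list and Bst2 (0.96) of the plasmacytoid list rose in 33D1 DCs. Cd24a was also higher in DEC205 than in 33D1 DCs of wild-type mice. Without the mixed arrays, and so with fewer arrays, it had 0.65 and was not called. Of 29 members, 27 and 28 lay above 0. The ligand and the tumour cannot be told apart here, and the list lost its call with an estimated correlation in both subsets (adjusted p = 0.288 and 0.1).

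Other splits of the arrays were tried for each count. A split that mixes groups adds their real differences to the spread, which can lower its count, so these counts leave chance undecided. For 3 arrays against 3, the 10 splits are too few for a share under 0.05: in each such contrast only 1 split, the real one, reached its count. The real and the highest other counts were 3046 and 1 between the subsets in wild-type mice, 3105 and 1 in Flt3L mice, 133 and 0 for Flt3L in 33D1 DCs, and 280 and 2 in DEC205 DCs. Between CD8 and CD4 T cells they were 429 and 220, the latter for a split that set apart the 3 T cell arrays with the highest median signals (204.5, 192.3 and 202.9). For B minus T cells 1 of 84 splits, the real one, reached 3568, and the highest other, with the same 3 arrays apart, gave 2942. For the restricted sets 1 of 100 regroupings, the real one, reached 244 and 347, and the highest others gave 12 and 4.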

How the results depend on the processing

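The settings without the mixed or the brightest arrays, the covariate and the block within the Flt3L DC arrays were chosen only after results were seen, and the mixed-array setting first left out only DEC205 replicate 3 before it was widened. Values of the named genes under the other settings numbered 16830, of which 16196 counted as kept, 490 no longer passed, 144 newly passed and 0 reversed. Only 305 of the 760 pairs of a named gene and a contrast were called. A pair called neither way counts as kept, so the 490 are a larger share of the calls than of all values. For Flt3L in 33D1 and DEC205 DCs 167 and 159 values no longer passed, where 29 and 42 named genes were called. Of 900 list values under other settings 854 counted as kept and 21 no longer passed. Of 900 with an array left out 839 counted as kept and 34 no longer passed. With an estimated correlation 88 of 125 counted as kept, 37 no longer passed and 0 newly passed. A list that passed neither way counts as kept, so the lost values are a larger share of the passes. The number of arrays and the signal over background limit the precision of low genes. The cause was not tested for any change below except where fewer arrays or more probe sets were tested.

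With an estimated correlation the MHC class I shifts of -0.69 in wild-type and -0.54 in Flt3L mice (adjusted p = 0.0711 and 0.13) and the class II shift of 0.59 in Flt3L mice (0.0522) no longer passed. The class II shift of wild-type mice newly passed at 0.35 without the brightest wild-type DC arrays, 0.36 without the mixed arrays, 0.35 with the array median as a covariate, 0.24 with no filter, 0.28 with no offset and 0.52 with quantile normalization. The immediate early list changed sign in the difference between the subset contrasts, from 0.46 to -0.04 without the mixed arrays. Of these arrays, wild-type DEC205 replicate 3 had a mean of 12.77 for this list, against 11.8 and 11.55 in its fellows. Leaving it out thus lowered the level of its group. The cell cycle list newly passed there at -0.25, from -0.02, and the cause was not tested.

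With all probe sets, 5212 were called between the subsets in wild-type mice, 5468 in Flt3L mice, 6547 in B minus T cells and 9 in the difference between the subset contrasts, and 473 and 619 were restricted to 33D1 and DEC205 DCs. With a log2 difference of at least 2 the restricted sets held 87 and 98 genes. CD8 minus CD4 T cells gave 250 genes with median centring and 215 with only the groups compared. The difference between the subset contrasts gave 6 genes without the brightest arrays, 3 without the mixed arrays, 50 with array weights, 4 with the mean of probe sets, 3 with median centring, 6 with no intensity trend, 2 with no offset and 29 with the offset at the median. The Flt3L contrast in 33D1 DCs gave 69 without the brightest arrays, 80 without the mixed arrays, 427 with array weights, 63 with median centring, 85 with no trend and 282 with only the groups compared. In DEC205 DCs it gave 153 without the brightest arrays, 572 with array weights and 90 with median centring.

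With the replicate number as a block over all arrays, the difference between the subset contrasts gave 8 genes, and no other count of calls moved by over 1.5 times. With 1 array left out the counts ran from 2518 to 2652 between the subsets in wild-type mice, 2563 to 2729 in Flt3L mice, 3057 to 3817 in B minus T cells, 287 to 411 in CD8 minus CD4 T cells, 3 to 13 in the difference between the subset contrasts, 51 to 110 and 93 to 214 for Flt3L in 33D1 and DEC205 DCs, and 225 to 258 and 326 to 355 in the restricted sets. The class II shift of wild-type mice ran from 0.22 to 0.40.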

Other observations

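No test in this part was chosen after its result was seen. The subsets also differed in receptors that take up or sense antigen. Of 17 C-type lectins and related receptors 6 were higher and 4 lower in wild-type 33D1 DCs (7 and 4 adjusted over the list alone), with Clec4a3 at 3.17 ± 0.23 and Clec4a2 at 4.18 ± 0.31, while the list as a whole did not pass (median 0.30, camera adjusted p = 0.362). Of 18 Toll-like receptors and adaptors 5 were higher and 3 lower (the same adjusted over the list alone), with a median of -0.03, a mean of 0.11 and an adjusted p of 0.932. Tlr7, a receptor of single-stranded RNA (3.61 ± 0.37), and Tlr1 (3.58 ± 0.24) were higher in 33D1 DCs, and Tlr3 (-4.98 ± 0.27) and the adaptor Tirap (-1.14 ± 0.18) were higher in DEC205 DCs. In Flt3L mice the counts were 8 and 3 for the lectins and 5 and 4 for the Toll-like receptors.

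Of 21 genes of costimulation and DC maturation 5 were higher and 5 lower in wild-type 33D1 DCs (6 and 5 adjusted over the list alone, median 0.20, camera adjusted p = 0.608). The NF-kappaB subunit Relb (2.42 ± 0.18) and Cd274, which encodes PD-L1 (2.76 ± 0.26), were higher, and the costimulatory ligand Cd86 (-2.14 ± 0.23) and the cytokine Il15 (-1.87 ± 0.20) were lower. Of 23 chemokines and receptors 5 were higher and 8 lower (7 and 9 adjusted over the list alone, median -0.06, adjusted p = 0.189). Cxcl9, a ligand of Cxcr3 (-5.20 ± 0.19), Ccr9 (-3.45 ± 0.26) and Cxcl16 (-2.24 ± 0.19) were lower. In Flt3L mice Ccr6 was higher in 33D1 DCs (3.91 ± 0.32), and the chemokine list had 8 genes higher and 7 lower.

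A hypothesis formed before its test held that 33D1 DCs share genes with CD4 T cells, and DEC205 DCs with CD8 T cells. Of the genes called both between the wild-type subsets and between the T cell groups, 55.45% of 211, Cd4 and Cd8a among them, went the same way (Fisher's exact test, p = 0.131), and in Flt3L mice 56.16% of 219 did (p = 0.0794). The test did not decide.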
